A study of Mus musculus with 7 samples.

How the data were processed

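Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse embryonic stem cells. Of the 7 samples, 3 had a peak list that was analysed here, with 1 library per group: SET precipitated with an anti-SET antibody from R1 cells, and HA-tagged SETα and HA-tagged SETβ precipitated with an anti-HA antibody from KH2 cells. R1 and KH2 are mouse embryonic stem cell lines. Per the labels' protocols, expression of the tagged isoforms was switched on with doxycycline at 1 μg/mL for 8 hours. The numbering of samples in that protocol text did not match the order of the samples, so the treatment was assigned only to the SETα and SETβ libraries, whose own labels carry it. The 2 input samples and the 2 samples precipitated with an antibody against linker histone H1 were not analysed here.

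Per the submitters' processing notes, the tools were Bowtie 0.12.7, a short-read aligner, and MACS 1.4, a peak caller, and the genome build was mm9. The notes give neither the parameters nor the role of the input libraries, and the read depth of each library is not given in the sources used here. The deposited lists hold a chromosome, a start, an end, a peak name and the authors' peak score, 1 list per library. The scale of the score is not stated in the files. The lowest score was 40 or 40.01 in each list, which would be a call threshold of 0.0001 if the score is -10 times the base-10 logarithm of the p-value. Such a score rises with sequencing depth, so it was used to rank or divide peaks within a list. Where lists are set side by side by score class, the classes have the same limits but need not mean the same strength of signal, and that comparison was repeated with classes by rank within each list. For the same reason the number of peaks in 2 lists cannot be compared as an amount of binding. Because the depth is unknown, no interval on the signal of a peak can be given. Intervals on shares of peaks are 95% Wilson intervals, those on differences of shares are 95% Newcombe intervals, and those on ratios of density are exact binomial limits. All of them cover the counting of peaks only, and peaks of 1 library are not replicates.

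Peaks of different lists were called overlapping when they shared at least 1 bp. For the overlap of 2 lists, the peaks of the shorter list were placed at random 1000 times within the span of their own chromosome, with their widths kept, and the one-sided permutation p is the share of placements with as many overlaps. The smallest p such a test can give is 0.001. Values for the 3 pairs of lists were adjusted by the Benjamini-Hochberg method. The span of a chromosome ran from the first start to the last end over the 3 lists. Peaks of a list were called neighbours when they lay within 10 kb of each other, and their share was set against 1000 placements with a two-sided permutation p. The distribution over chromosomes was tested with a chi-square statistic against the pooled counts of the 3 lists, with p from 10000 random multinomial draws, and between pairs of lists by reassigning peaks to the lists 10000 times. The smallest p of these tests is 0.0001. Shares of peaks were compared with Fisher's exact test, two-sided. The densest window of 1 Mb in each list was compared with the densest window in each of 1000 placements. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a fixed random seed.

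The tests were tried on simulated lists with the numbers of the SETα and SETβ peaks, in 100 simulations of 99 placements each. The overlap test reached p at or under 0.05 in 3 simulations without planted overlap and in 100 with 60 planted overlaps. The neighbour test did so in 2 simulations without and 100 with planted neighbours. The chromosome test did so in 3 simulations without a change and in 99 with 1 chromosome at 2 times its density. Its simulated counts were drawn from and tested against the chromosome spans, not the pooled lists. Simulated peaks were placed evenly, as in the random placements, without the clustering of the real lists. The simulations therefore check the computation and not the error rate on lists such as the real ones.

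The regions named in the text follow a rule fixed before the data were examined: the 10 peaks with the highest score in each list, the 10 regions shared by the SETα and SETβ lists with the smallest sum of ranks, the 5 highest peaks of each isoform list without overlap in the other, and the 10 regions of all 3 lists with the smallest sum of ranks. Regions chosen after their values were seen are named as such. Positions are on mm9 and count from 1. The gene table used here is on another build, GRCm38, and coordinates were not moved between builds, so peaks were not assigned to genes. The planned tests of promoters, annotation classes, gene lists, sequence content and motifs, and the genes set aside to be named whatever they showed, were therefore not analysed here. The table served only to count the protein-coding genes on each chromosome.

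Alternatives fixed before the data were examined were a score of at least 100, lists cut to equal length, merging of peaks within 1 kb, autosomes only, reciprocal overlap of 50%, a distance of at most 1 kb, random shifts of 10 to 100 kb in place of random placement, and neighbours within 100 kb. Leaving out a replicate was not possible with 1 library per group.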

Results

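The series asked where SET, a histone-binding chaperone protein, and its isoforms SETα and SETβ are bound in the genome of mouse embryonic stem cells. ChIP-seq peak lists of 3 libraries were compared. The SET list from R1 cells, made with an antibody against SET, held 3446 peaks that covered 658 kb. The lists of the HA-tagged isoforms induced in KH2 cells held 1186 peaks over 255 kb for SETα and 1566 peaks over 392 kb for SETβ. Each group had 1 library, so no difference between the lists has a replicate check, and the depth of the libraries is unknown.

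Peaks in all 3 lists were short and most scored low. The median width was 198 bp for SET (interquartile range 162 to 222 bp), 223.5 bp for SETα (155 to 260 bp) and 256 bp for SETβ (181 to 305 bp). The authors' median score was 47.4 in the SET list, 57.2 in the SETα list and 55.5 in the SETβ list. Scores lay under 60 for 2960 SET peaks (85.9%), 685 SETα peaks (57.8%) and 1016 SETβ peaks (64.9%). Scores of at least 100 were reached by 82 SET, 158 SETα and 252 SETβ peaks.

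The first question was where endogenous SET was found in R1 cells. The highest scores of the SET list fell in a short stretch of chromosome 2, at positions 98506390 to 98507495 (score 987) and 98502318 to 98503140 (508). They were followed by a 115 bp peak on chromosome 10 at 92960949 to 92961063 (382), a further peak of the same stretch of chromosome 2 at 98505188 to 98505384 (373) and an 89 bp peak on chromosome 9 at 115051097 to 115051185 (351). The other members of the top 10 lay on chromosome 10 at 106376378 to 106376481 (293), chromosome 15 at 66506015 to 66506263 (286), chromosome 2 at 167720898 to 167720999 (283), chromosome 19 at 22196124 to 22196220 (274) and chromosome 7 at 86536823 to 86536924 (251). Each of these 10 peaks overlapped a peak in both isoform lists. Sites that gather reads in any library would recur in this way too. A peak list of an input library was not used here, so such sites cannot be told from SET binding sites among these peaks. Of the whole list, 3262 of the 3446 SET peaks (94.7%) overlapped neither isoform list. Their median score was 47.3, near the lowest score of 40.01, against 102.2 for the 77 SET peaks that overlapped both. With library depths unknown, this is absence of a call in the isoform lists and does not mark sites particular to SET.

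The second question was how far the SETα and SETβ sites coincide in KH2 cells. Of the 1186 SETα peaks, 178 (15.01%, 95% Wilson interval 13.1 to 17.2%) overlapped a SETβ peak, and 177 of the 1566 SETβ peaks (11.3%, 9.83 to 12.97%) overlapped a SETα peak. Random placement of the SETα peaks gave 0.442 ± 0.655 overlaps (SD over 1000 placements) and at most 3 (permutation adjusted p = 0.001, the smallest the placements can give). Shifts of 10 to 100 kb gave a random mean of 1.94, so the observed count was 91.6 times that mean (permutation adjusted p = 0.001). Both lists were made with the same antibody and cell line, and no anti-HA library from cells without a tagged isoform is among the samples. Background common to both libraries cannot therefore be told from shared binding. Most peaks of either isoform list had no counterpart in the other. The shared SETα peaks were shorter and higher, with a median width of 146.5 bp and a median score of 100.3, against 230 bp and 55.5 for the unshared ones. The shared SETβ peaks had medians of 177 bp and 106.9, against 263 bp and 54.3.

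Among the regions shared by the isoforms, the stretch of chromosome 2 near position 98506374 again stood first. Its leading peak had a score of 3100 in both lists, the next 2120 for SETα and 2274 for SETβ, and the one between them 922 and 832. Whether 3100 is an upper limit of the score is not given, so the equal values need not mean equal signal. The region at 103599068 to 103599311 on chromosome 6 scored 736 for SETα and 762 for SETβ. The region at 35112778 to 35113179 on chromosome 9 scored 589 and 773. The remaining shared regions were on chromosome 16 at 30829596 to 30829741 (295 for SETα, 432 for SETβ), chromosome 7 at 86536817 to 86536946 (408 and 300.2), chromosome 10 at 92960947 to 92961085 (500.2 and 268.5), chromosome 2 at 57481915 to 57482152 (294 and 299) and chromosome 11 at 56989568 to 56989711 (362 and 268). The peak at 7797280 to 7797410 on chromosome 17 (302), in the top 10 of SETα, was also shared, as were 2 peaks in the top 10 of SETβ, at 68090668 to 68090947 on chromosome 17 (498) and at 30628817 to 30628975 on chromosome 4 (438).

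Some high peaks were listed for 1 isoform. For SETα without a SETβ peak, the highest were on chromosome 2 at 181747456 to 181747746 (score 341), chromosome 8 at 72397884 to 72397997 (246), chromosome 14 at 68056040 to 68056144 (202), chromosome 9 at 3032378 to 3032734 (184) and chromosome 2 at 98034371 to 98034536 (183). None of these 5 overlapped a SET peak. For SETβ without a SETα peak, the highest were on chromosome 11 at 64496023 to 64496151 (506), chromosome X at 62071440 to 62071602 (441), chromosome 16 at 84490232 to 84490353 (419), chromosome 11 at 29057737 to 29057926 (314) and chromosome 14 at 18466143 to 18466283 (235). Those on chromosomes X and 16 and the one at 29057737 on chromosome 11 overlapped SET peaks, with SET scores of 218, 182 and 112. With 1 library per isoform, absence from a list is absence of a call at an unknown depth and not a measured difference in binding.

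The third question was how the tagged isoforms compare with endogenous SET. SET peaks overlapped 114 SETα peaks (9.61%, interval 8.06 to 11.4%) and 147 SETβ peaks (9.39%, 8.04 to 10.9%). Random placement gave 0.705 ± 0.816 and 1.09 ± 1.01 overlaps (SD over 1000 placements; permutation adjusted p = 0.001 for each, the smallest possible), and shifts of 10 to 100 kb gave means of 1.13 and 1.60. The share overlapping SET was 0.23 percentage points higher for SETα than for SETβ, with a 95% interval from -1.96 to 2.48 points (Fisher's exact test, p = 0.84, adjusted p = 1 over 3 comparisons). When all lists were cut to their 1186 highest peaks, the difference, SETα minus SETβ, was -3.04 points (interval -5.47 to -0.62, Fisher's exact p = 0.017). With only the isoform lists cut, a choice made after seeing the data, it was -2.36 points (-4.87 to 0.14, Fisher's exact p = 0.074). Both cuts left the 1186 SETα peaks whole and removed only the lowest-scoring peaks from the SETβ list. Of the SETβ peaks under a score of 60, 1.28% overlapped SET, so such a cut raises the SETβ share by itself. These differences are therefore not evidence that the isoforms differ. The antibody and the cell line both differ between the SET list and the isoform lists, and the tagged isoforms were induced with doxycycline. Their level relative to endogenous SET was not measured here.

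Overlap with SET was concentrated in the peaks that the isoforms shared. Of the 178 SETα peaks that overlapped SETβ, 78 (43.8%, interval 36.7 to 51.2%) overlapped SET, against 36 of the 1008 other SETα peaks (3.57%, 2.59 to 4.90%; Fisher's exact p = 2.9e-44). For SETβ these numbers were 77 of 177 (43.5%, 36.4 to 50.9%) and 70 of 1389 (5.04%, 4.01 to 6.32%; Fisher's exact p = 1.8e-40). The shared peaks also scored higher, with medians of 100.3 against 55.5 for SETα and 106.9 against 54.3 for SETβ. The comparison was not divided by score, so whether sharing matters beyond score was not tested. The 78 SETα peaks found in all 3 lists had a median width of 136 bp and a median score of 126, and their midpoints lay a median of 8 bp from that of the SET peak. Besides the regions of chromosomes 2, 6, 7, 10 and 11 given above, the leading regions of all 3 lists were on chromosome 2 at 167720874 to 167721006, chromosome 3 at 124106931 to 124107064 and chromosome 4 at 30628833 to 30628960. A further 100 SETα peaks overlapped SETβ and not SET.

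Overlap rose with the score in every list. Of the SETα peaks that scored under 60, 3.07% (interval 2.01 to 4.64%) overlapped SETβ and 2.63% (1.67 to 4.12%) overlapped SET. Of the 28 SETα peaks that scored 200 or more, 89.3% (72.8 to 96.3%) overlapped SETβ and 75% (56.6 to 87.3%) overlapped SET. For SETβ, the share overlapping SETα rose from 2.85% under 60 to 79.5% of the 44 peaks at 200 or more. All 19 SET peaks that scored 200 or more overlapped SETβ, and 18 of them overlapped SETα.

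**Figure D1:**
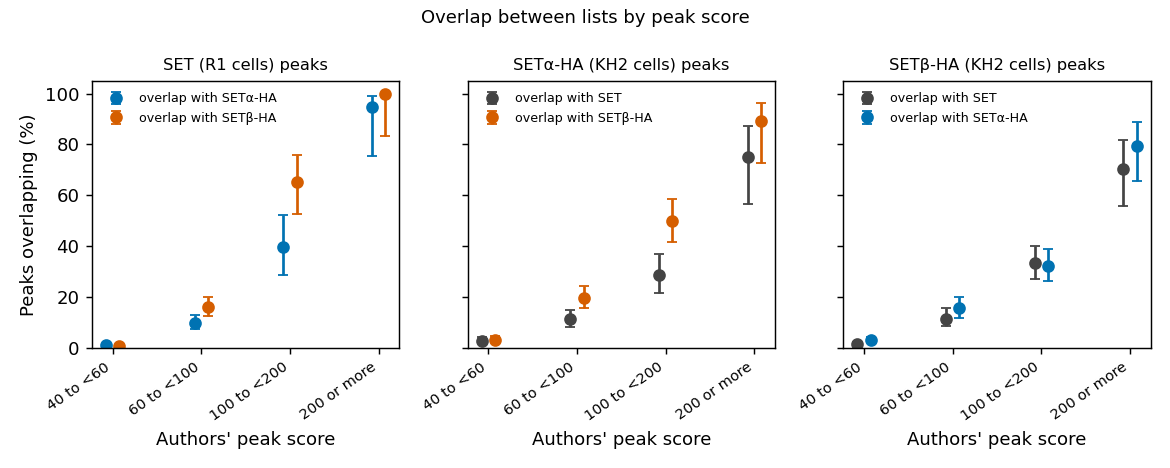
Share of peaks in each list (panels) that overlap each of the other lists (colours), in percent, by class of the authors' peak score. Points are shares and bars are 95% Wilson intervals. In all 3 panels the shares are at most 3.07% for scores of 40 to under 60 and at least 70.5% for scores of 200 or more.

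The fourth comparison was of where on the chromosomes the lists lay. SETα and SETβ peaks were dense on chromosomes 1 and 8, and SET peaks were not. SETα had 0.852 peaks per Mb on chromosome 1 and 1.08 on chromosome 8, which was 2.05 times (exact limits 1.73 to 2.43) and 2.60 times (2.16 to 3.12) its density on the other autosomes. SETβ had 1.23 and 1.27 peaks per Mb, or 2.24 times (1.94 to 2.58) and 2.31 times (1.95 to 2.73). SET had 1.31 and 1.06 peaks per Mb, or 0.91 times (0.80 to 1.03) and 0.74 times (0.62 to 0.87). At scores of at least 100, the ratio for chromosomes 1 and 8 together was 0.89 for SETα (0.52 to 1.45) and 1.09 for SETβ (0.74 to 1.56). SET peaks were densest among the autosomes on chromosomes 11 (1.97 per Mb), 14 (1.79) and 17 (1.78). Chromosome X was sparse in all 3 lists, at 0.13 times the density of the autosomes other than 1 and 8 for SET (0.09 to 0.19), 0.25 times for SETα (0.15 to 0.41) and 0.28 times for SETβ (0.18 to 0.42). For scores of at least 100, with 2, 2 and 9 peaks on X, the ratio was 0.39 for SET (0.05 to 1.45), 0.19 for SETα (0.02 to 0.69) and 0.56 for SETβ (0.25 to 1.08). For SET and SETβ those limits include 1. All 3 lists also held peaks on chromosome Y (27 SET, 5 SETα and 5 SETβ peaks). The number of copies of chromosome X in these cells was not tested here. A ratio of 1 need therefore not be the value without a difference in binding, and low ratios on X are not shown to reflect binding.

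The distribution over chromosomes differed between SET and SETα (chi-square 206 on 20 degrees of freedom, permutation adjusted p = 0.00012) and between SET and SETβ (208, adjusted p = 0.00012). Between SETα and SETβ it did not pass the test (20.5, permutation p = 0.43). Against the pooled lists, each list deviated (chi-square 128 for SET, 91.3 for SETα and 88.3 for SETβ, adjusted p = 0.00012 for each over 6 comparisons). With lists of equal length the SETβ list no longer did (17.8, p = 0.6 by random draws, not permutation). With chromosomes 1 and 8 left out, SETα still deviated from the pooled lists (random multinomial draws, not permutation, 37.9, p = 0.0037), while SET (28.2, p = 0.06) and SETβ (23.0, p = 0.19) did not pass it. The pooled lists hold more SET peaks (3446) than SETα and SETβ peaks together. Against the span of each chromosome, a reference chosen after seeing the data, all 3 lists deviated (599 for SET, 318 for SETα and 338 for SETβ, and on the autosomes alone 87.0, 230 and 248; p = 0.0001 for each by random draws, not permutation). With scores of at least 100, none of the 3 lists passed the test against the pooled lists by random draws, not permutation (SET p = 0.52, SETα p = 0.97, SETβ p = 1).

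**Figure D2:**
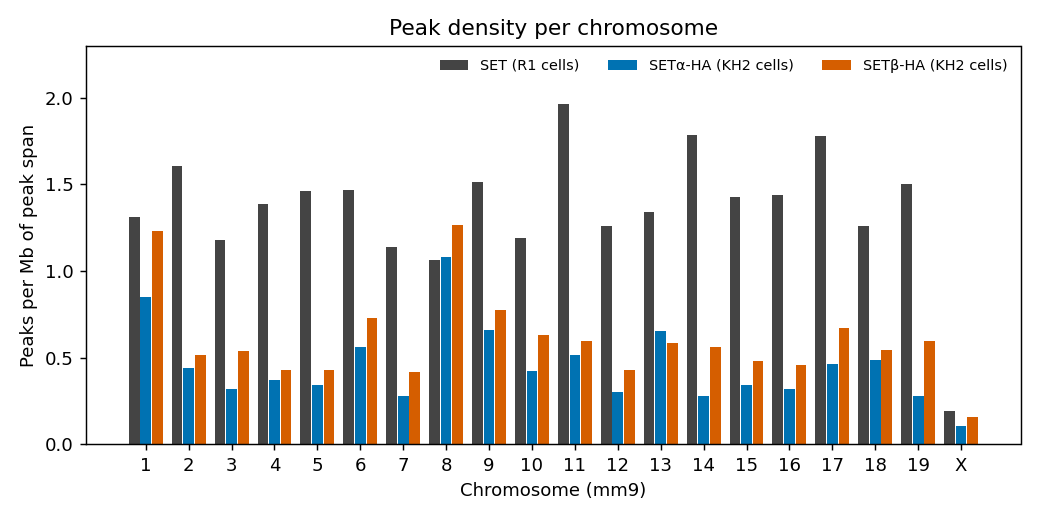
Peaks per Mb of chromosome span (bars, from 0) in the SET, SETα and SETβ lists on chromosomes 1 to 19 and X of build mm9; the span runs from the first to the last peak of the 3 lists. Peaks of all scores are counted. The SETα and SETβ bars are tallest on chromosomes 1 and 8, at 0.852 and 1.08 per Mb for SETα and 1.23 and 1.27 per Mb for SETβ.

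The fifth comparison was of clustering within each list. Another peak of the same list lay within 10 kb of 161 SET peaks (4.67%, interval 4.02 to 5.43%), 70 SETα peaks (5.90%, 4.70 to 7.39%) and 89 SETβ peaks (5.68%, 4.64 to 6.94%). Random placement gave 107 ± 13.8 for SET, 14.1 ± 5.15 for SETα and 23.6 ± 6.77 for SETβ (SD over 1000 placements), so observed counts were 1.503, 4.98 and 3.77 times the random ones (permutation adjusted p = 0.004, 0.003 and 0.003). Without the 5 densest windows of each list, a choice made after seeing the data, the shares for SETα and SETβ fell to 2.50% and 2.67% and stayed above placement. Placement was even over the span of each chromosome and did not leave out stretches where no peak can be called. Such stretches would raise the observed count above placement too. Their part in the excess, which was smallest for SET, was not tested.

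Both isoform lists had dense windows on chromosomes 8 and 9. The window from 3 to 4 Mb on chromosome 9 held 23 SETα and 22 SETβ peaks, against 3 SET peaks. No random placement of either isoform list put more than 9 peaks in any window of 1 Mb (permutation adjusted p = 0.0015 for each). Between 2999969 and 3038289, near the start of the assembled sequence, lay 22 peaks of each isoform list. From 2.9 to 3.1 Mb, SET too was 6.61 times as dense as on the whole chromosome. Even placement cannot tell binding from sites that gather reads in any library. The window from 19 to 20 Mb on chromosome 8 held 11 SETα and 10 SETβ peaks and 1 SET peak. For SET, the densest autosomal windows held 9 peaks, which did not pass the test against placement (permutation adjusted p = 0.074).

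On chromosome 13, the region from 21 to 24 Mb, chosen after its values were seen, held 23 SETα peaks and 24 SETβ peaks, 11 of each overlapping the other isoform, and 6 SET peaks. That was 11.7 and 13.7 times the density of the whole chromosome for SETα and SETβ and 1.49 times for SET. In random placement, no window of 3 Mb on any autosome held more than 13 SETα or 15 SETβ peaks (permutation adjusted p = 0.0015 for each). The isoform peaks fell into groups at 21321047 to 21380343 (3 SETα and 4 SETβ peaks), 21947689 to 22113149 (10 and 5) and 23362140 to 23622511 (9 and 15), and 1 SETα peak at 22690460 to 22690570 stood alone.

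**Figure D3:**
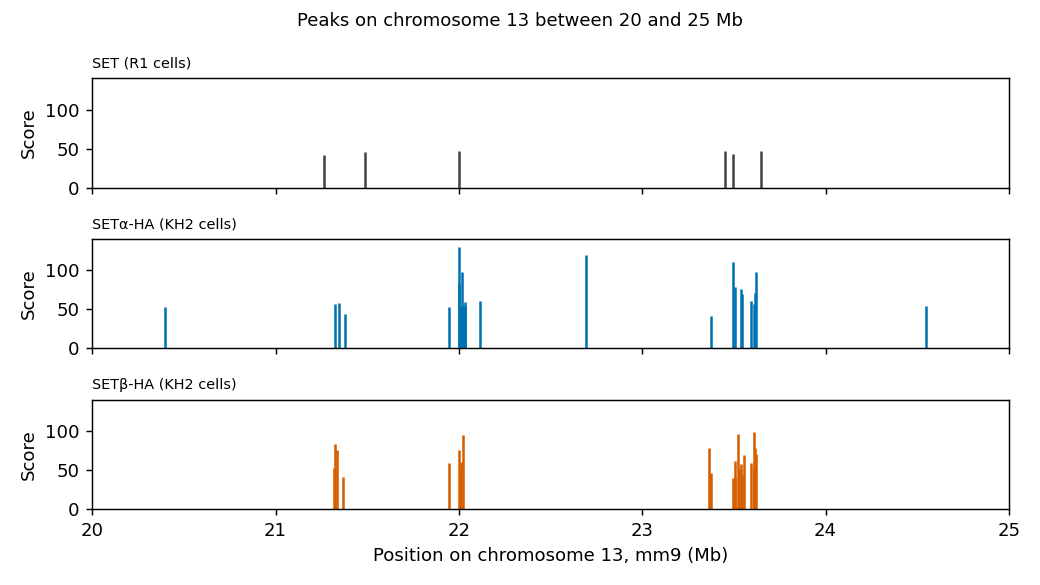
Peaks of the SET, SETα and SETβ lists (panels) on chromosome 13 of build mm9 between 20 and 25 Mb; each line is 1 peak at its midpoint and its height is the authors' peak score. The 23 SETα and 24 SETβ peaks between 21 and 24 Mb stand mostly in the same 3 groups, with 6 SET peaks in that range.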

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

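The tests in this part were chosen after the result was seen, except those on high isoform peaks that overlap no SET peak and on SETα peaks scoring under 60 that overlap SET.

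The share of peaks on chromosomes 1 and 8 changed with peak score in the KH2 lists and not in the same way in the R1 list. The log2 odds ratio of lying on these chromosomes, for peaks scoring under 60 against those scoring at least 100, was 1.79 for SETα, 1.39 for SETβ and -0.31 for SET. The difference from SET was 2.10 for SETα and 1.70 for SETβ (permutation of list labels within score classes, adjusted p = 0.0032 and 0.0052). Because a score need not mean the same in lists of different depth, classes by rank within each list (lower 50% against top 10%) were also compared. The log2 odds ratio was then 1.81 for SETα, 1.69 for SETβ and 0.24 for SET, so the sign for SET depends on the classes, and the differences from SET were 1.56 and 1.45 (permutation adjusted p = 0.0039 for each).

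A few dense windows do not account for the excess, since without the 5 densest windows on chromosomes 1 and 8 the density there was still 2.06 times that on the other autosomes in the lower of the isoform lists (limits 1.79 to 2.36). The excess lay in weak peaks: under a score of 60 the density was 3.19 times (2.70 to 3.75) for SETα and 2.81 times (2.45 to 3.22) for SETβ, and at 100 or more it was 0.89 times (0.52 to 1.45) for SETα and 1.09 times (0.74 to 1.56) for SETβ. An excess of the same size at every score is argued against, since the ratio under 60 was 2.59 times that at 100 or more for SETβ (limits 1.75 to 3.92) and 3.57 times for SETα (2.13 to 6.26). Weak peaks called more often along the whole of both chromosomes would give these values: weak peaks were denser than on the other autosomes in all 10 equal parts of both chromosomes in both lists, by 1.08 to 6.11 times, though the lowest parts held few peaks. The condition on parts was set after the values were seen. So was a condition of even spread, which was added, removed, restored and then dropped because it used peaks of all scores (SETβ along chromosome 8, adjusted p = 0.046 by random multinomial draws, not permutation) and an excess along a whole chromosome need not be even; with it, this explanation would have stayed open. Weak peaks alone did not pass the test for uneven spread (lowest adjusted p = 0.17 by random draws, not permutation). Extra copies of chromosomes 1 and 8 in the induced KH2 cells may be one source, which neither a karyotype nor an input track was used here to test. A smaller excess of high peaks stays open, because high isoform peaks that overlap no SET peak (246 on the autosomes in both lists together) had a ratio of 1.11 with limits of 0.75 to 1.58, and the upper limit did not fall under the bound of 1.5 set before the test. A site called in both isoform lists was counted in each, so these limits, which treat peaks as independent, are too narrow. A difference between the cell lines in the binding of weak sites was not tested.

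The strongest peaks recurred across both antibodies and both cell lines. Of the SETα peaks at 200 or more, 75% (56.6 to 87.3%) overlapped a SET peak. Sites that gather reads in any library, such as repeats collapsed in the assembly, may account for this and stay open, because that share restates the pattern and a peak list of an input library was not used here. Binding sites of SET present in both lines may account for it as well: SETα peaks scoring under 60 also overlapped SET peaks, 41.9 times as often as random placement (18 against 0.43, permutation p = 0.001), 23.0 times as often as local shifts (0.781), and 22.4 times with both lists under 60 (8 against 0.357). Read-gathering sites with lower scores could give such overlaps too.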

How the results depend on the processing

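Settings without chromosomes 1 and 8, without the densest windows, with scores under 60, without SET-overlapping peaks, with only the isoform lists of equal length and against the chromosome span were added after seeing the data. Of 97 results under alternative settings, 85 kept their side of the threshold and, except for the chi-square results, which have none, their direction, or stayed within 1.5 times for numbers of peaks. All results on overlap beyond placement and on clustering were among them, which raises this number. The difference between isoforms was kept in 6 of 9 settings. The chromosome result was kept in 5 of 7 settings for SET, 6 of 7 for SETα and 4 of 7 for SETβ. The 3 pairs of lists overlapped more than random placement in every setting run, though the SETα share overlapping SETβ ranged from 1.75% (both lists under a score of 60) to 45.6% (scores of at least 100), and was 9.33% without peaks that overlap SET. The share overlapping SET ranged from 1.17 to 21.5% for SETα and from 0.39 to 22.6% for SETβ. Clustering exceeded placement, which was even over the span of each chromosome, in every setting run. With scores of at least 100, 82 SET, 158 SETα and 252 SETβ peaks remained, and the chi-square over chromosomes dropped to 18.9 for SET, 10.0 for SETα and 5.11 for SETβ, none past the threshold; fewer peaks enter that test. Without chromosomes 1 and 8 it was 28.2 for SET and 23.0 for SETβ, and with lists of equal length it was 17.8 for SETβ (p = 0.6 by random draws, not permutation), again not past the threshold. The difference between isoforms in overlap with SET reversed to -1.10 percentage points with scores of at least 100 (Fisher's exact p = 0.81), for a cause not tested. It was -3.04 points with all 3 lists of equal length (Fisher's exact p = 0.017). With only the isoform lists of equal length it was -2.36 points (Fisher's exact p = 0.074). Cutting to equal length left the SETα list whole and removed only the lowest-scoring SETβ peaks, few of which overlapped SET. That raises the SETβ share by itself, so these reversals are not evidence that the isoforms differ. The difference did not pass the threshold in any other setting. No paired analysis was possible because each group had 1 library. The tests that need an annotation or a genome of build mm9 were not run. Depth is unknown, so whether more reads would raise the overlap of weak peaks was not testable here.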

Other observations

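The test of gene density in this part was chosen after its result was seen, and so were the other values here.

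Chromosome 6 was unevenly covered in both isoform lists. From 61.7 to 120 Mb, SETα had 0.19 peaks per Mb against 0.81 on the rest of the chromosome, and SETβ had 0.26 against 1.05. SET had 1.55 against 1.41. Copy number in the KH2 cells was not tested here, for this region or for chromosomes 1 and 8. Over 10 equal parts of the chromosome, counts departed from even for SETα and SETβ (chi-square with random draws, adjusted p = 0.0009 for each) and did not pass the test for SET (adjusted p = 0.29). Along chromosome 1 the counts did not pass the same test, by random draws and not permutation, for SETα (adjusted p = 0.21) or SETβ (0.53) and passed it for SET (0.046). Along chromosome 8 they passed it for SETβ (0.046), with 1.56 peaks per Mb from 54.4 to 106 Mb against 1.07 elsewhere, and did not for SETα (0.10) or SET (0.80).

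Peak density per autosome was similar in the 2 isoform lists. Across the 19 autosomes, which are not replicates, Pearson's r was 0.91 (permutation adjusted p = 6e-05) and Spearman's rho 0.75 (0.00096), and r was 0.70 without chromosomes 1 and 8. Between SET and SETα the relation did not pass the test (r = -0.22, adjusted p = 0.43; rho = 0.01, adjusted p = 0.97), nor between SET and SETβ (r = -0.19, adjusted p = 0.43; rho = 0.16, adjusted p = 0.75), and r turned to 0.19 and 0.34 without chromosomes 1 and 8. Whether the isoform lists were called against an input is not given in the sources used here. Only 1 input sample was from KH2 cells, so lists called against a KH2 input would share it and not be independent.

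One hypothesis was that gene-rich chromosomes hold more SET peaks. The density of SET peaks and that of protein-coding genes across the 19 autosomes had a Pearson's r of 0.43 (permutation p = 0.072, adjusted p = 0.22 over 3 lists) and a Spearman's rho of 0.40 (adjusted p = 0.26), and r was 0.53 without chromosomes 11 and 7. The relation did not pass the test. For SETα and SETβ, r was -0.15 and -0.14.

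Many peaks carried the same score. In the SET list 268 peaks scored exactly 47.34 and 185 scored 53.44, and the 10 commonest scores covered 23.3% of SET, 26.1% of SETα and 26.4% of SETβ peaks. Peaks of middle scores were narrower than weak ones: SET peaks scoring 80 to under 200 had a median width of 93 bp against 203 bp under a score of 60, and the same medians were 122 and 247 bp for SETα and 147 and 280 bp for SETβ. At scores of 200 or more the medians were 115 bp for SET, 141.5 bp for SETα and 190.5 bp for SETβ, wider than at 100 to under 200 (94, 117.5 and 144 bp), and the highest-scoring peak of each list was 1106, 1138 and 1171 bp wide.

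On chromosome Y, the window from 2 to 3 Mb held 24 SET peaks, 5 SETα peaks and 5 SETβ peaks. On chromosome 9, the isoform peaks near the start of the assembled sequence lay between 2999969 and 3038289, with 18 of 22 SETα peaks overlapping SETβ. SET had 2 peaks from 2.9 to 3.1 Mb, and both overlapped SETα. Density there was 6.61 times that of the whole chromosome for SET, 166 times for SETα and 142 times for SETβ.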
